A study of Mus musculus with 2 samples.

How the data were processed

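H3K4me1, the histone H3 lysine 4 monomethylation that marks enhancers and the flanks of promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse stomach at embryonic day 14.5. Per the labels, stomachs of healthy embryos of both sexes were pooled, and there were 2 biological replicates of 1 group, each with technical replicates 1 and 2. No second tissue, stage or treatment was included, so the comparisons were between replicates, between genomic regions and between gene groups within the map.

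The authors aligned the reads to mouse assembly mm10 and deposited 4 lists of peaks: 1 for each replicate, 1 called on the pooled alignments of both replicates, and 1 replicated list derived from the pooled list and both replicate lists. Replicate 1 was called against 2 control alignments, replicate 2 against 1, and the pooled list against both. The signal value of each deposited peak was read as a ratio, the fold enrichment of the immunoprecipitate over the control, as computed by the authors. The authors also gave each peak a −log10 p-value and a −log10 q-value. The aligner, the peak caller, its thresholds and the rule behind the replicated list were not given in the sources used here. Every replicated peak was an unchanged entry of the pooled list.

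Peak scores were the authors' and served only to describe, rank or filter peaks within a list. Read depth was not given. The scores carried traces of it: between 42.3% and 61.3% of the peaks in the pooled and replicate lists lay on evenly spaced steps of fold (within 0.0002 of a step), and the p-values on these steps followed a Poisson background of 2.71 in replicate 1 and 2.03 in replicate 2, in units of scaled height in which 1 step, read as 1 fragment, was 1.0 and 0.761 high. On this reading the median summit of the peaks on the steps held 11 fragments in replicate 1, 13 in replicate 2 and 20 in the pooled list. The lists hold called peaks only, so a region without a peak is not shown to lack the mark.

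Positions were compared with the mm10 sequence and the GENCODE M21 annotation, using Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with plots in matplotlib 3.10.9. The 19 autosomes and the X were used. A peak was met in the other replicate when their overlap was at least 50% of either peak, and the same was computed for 20 random placements of the peaks on the same chromosomes outside assembly gaps. Wilson intervals at the 95% level were given for shares of peaks, and cover counting error only. Peak midpoints were assigned in order of priority to within 1 kb of a transcription start site (TSS), exon, intron or intergenic sequence, with 10 random placements for comparison. Coverage around protein-coding TSSs was read in 100 bp bins over 5 kb to each side, as the ratio of the bins within 0.2 kb to those 1 to 2 kb away. Promoters with a CpG observed to expected ratio over 0.6 and GC content over 50% within 500 bp of the TSS were called CpG-rich. Domains were peaks merged over gaps of 1 kb or less. Each Hox gene's stretch ran from its 3′ end to the 3′ end of the next Hox gene on its 5′ side, and paralogue groups up to 6 were called anterior and those from 10 posterior.

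For each gene, the measure was the number of bases covered by replicated peaks within 25 kb of its TSS, the most 5′ of its annotation. The median of each of 22 gene lists was set against 10000 random lists of equal size matched on gene length decile, in one-sided permutation tests of both tails. The 44 p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold, and 0.0001 is the smallest p these random lists can give. Genes are not replicates, so a percentile among random lists describes these libraries only. The lists were gastric epithelial regulators, mature gastric epithelial products, gastric mesenchyme regulators, signalling components, smooth muscle, mesothelial, endothelial, blood cell, enteric neural crest, squamous epithelium and spleen mesenchyme genes, and genes of pancreas, liver, intestine, skeletal muscle, cardiomyocytes, forebrain, retina and lens, germ line and housekeeping functions, with anterior HoxA and HoxB genes and posterior Hox genes apart. Hoxa5, Hoxb13, Hoxb5, Hoxd13, Nkx3-2 and Tcf21 each stood in more than 1 list.

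The lists, the comparisons, their settings and the rule for named genes were chosen before the data were examined. The rule named the members of each list with the most and the fewest covered bases and up to 2 more from the top, and the 20 genes with the most covered bases that were also among the 200 highest in each replicate, 1 per 50 kb. It also took the genes at the 10 widest domains, all Hox genes, and Barx1, Sox2, Gata4, Foxf1, Nkx2-5, Six2, Hnf4a, Pdx1, Cdx2, Trp63, Myod1 and Alb.

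Each result was recomputed without each replicate, which means from the peaks of the other replicate alone, and with peaks of a −log10 p of at least 5. Other alternatives were windows of 5 and 100 kb, a count of peaks in place of covered bases, random lists without matching or matched also on CpG class, other overlap rules, other promoter definitions and other merging gaps. Matching on regional GC content and gene density, leaving out X-linked genes, annotated Hox gene bodies and the pooled list for chromosomes were added after seeing the data. Differences between 6 pairs of gene lists, families of gene symbols with at least 15 loci and the repeat content of peaks were also examined only afterwards. Those pairs were compared by two-sided permutation of list membership with 100000 resamples.

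The procedures were tested on simulated data. Of 200 random lists, 5% had an unadjusted p under 0.05 for the upper tail and 4.5% for the lower tail, and 100% of 100 lists built from highly covered genes passed the upper tail. In a simulated pair of lists with 39.9% of peaks copied, 40.1% were found shared. The copies were shifted too little to miss their originals, so this checks the counting only. Likewise, the lists of highly covered genes do not give the power for shorter or less covered lists. No reads or signal tracks were analysed here. Values per replicate are given as mean ± SD with n = 2, and no test between the replicates was made.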

Results

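The monomethylated form of histone H3 lysine 4 (H3K4me1) was mapped in stomach from mouse embryos at day 14.5, in 1 group of 2 biological replicates made from pooled embryos of both sexes. The labels state no purpose beyond profiling this mark. Replicate 1 held 111848 peaks covering 38.7 Mb and replicate 2 held 115117 peaks covering 47.2 Mb, a mean of 113482 ± 2312 peaks (SD, n = 2). The list called on both replicates together held 137550 peaks, and the replicated list taken from it held 76102 peaks covering 48.5 Mb, or 1.89% of the assembled mm10 genome. Median peak width was 499 bp in the replicated list and 290.5 ± 23.3 bp (SD, n = 2) in the replicates. The median fold of immunoprecipitate over control, as given by the authors, was 3.44 in the replicated list, 3.19 in replicate 1 and 3.6 in replicate 2. Read depth was not given, and the evenly spaced fold values, with each step read as 1 fragment, put the median summit of the peaks on these steps at 11 fragments in replicate 1 and 13 in replicate 2.

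The most heavily marked locus in the replicated list of this stomach map was that of Rara (ENSMUSG00000037992), which encodes a retinoic acid receptor. Peaks covered 25.1 kb of the 50 kb around the Rara TSS in the replicated list, and 21.6 ± 1.44 kb (SD, n = 2) in the replicates, though in replicate 2 alone G430095P16Rik had more than Rara, 22766 against 22665 bp. Smad3, a transcriptional effector of TGF-β signalling, had 23.8 kb covered (20.1 ± 2.48 kb in the replicates, SD, n = 2), and Ncor2 (ENSMUSG00000029478), a nuclear receptor corepressor, had 22.5 kb (20.2 ± 3.21 kb, SD, n = 2). Smad7, an inhibitor of the same pathway, had 20.4 kb covered in 7 peaks, with 19.3 ± 0.945 kb in the replicates (SD, n = 2). The other 16 of the 20 named genes were G430095P16Rik, Bahcc1, Btg2, Mrpl23, Sema3f, Tgfbi, Ptk7, Igf2r, Ski, Zmiz1, Lrig1, Mn1, Hspg2, Cxxc5, Nr1d1 and Pmepa1, with 20.5 to 24.4 kb each. Across all 21755 protein-coding genes the median was 993 bp, the upper quartile was 2768 bp, and 15053 genes (69.2%) had at least 1 replicated peak. The strongest Rara peak lay in an intron at mm10 chromosome 11, 98938502 to 98946060 (fold 8.30), and the strongest Ncor2 peak in an intron at chromosome 5, 125156531 to 125161009 (fold 9.94, the highest in the replicated list). Smad3 (ENSMUSG00000032402) had its strongest peak in an intron at chromosome 9, 63752120 to 63755791 (fold 6.54), and Smad7 (ENSMUSG00000025880) at chromosome 18, 75372231 to 75376209 (fold 7.13), also intronic. The windows of neighbouring genes share peaks, so the covered length belongs to a locus and not to 1 gene.

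The 10 widest marked domains lay inside genes. The widest of all spanned 34.6 kb of Lrig1, which encodes a receptor-tyrosine-kinase antagonist, at chromosome 6, 94664157 to 94698776. The next were 22.7 kb in Zfhx3 (chromosome 8, 108715556 to 108738252), 21.8 kb in Smad7 (chromosome 18, 75371264 to 75393087), 21.6 kb in Notch1 (chromosome 2, 26481155 to 26502748) and 20.9 kb in Smad6 (chromosome 9, 63955904 to 63976834). Ssbp3 held 2 of the 10 widest, of 20.1 kb (chromosome 4, 106946995 to 106967077) and 18.4 kb (chromosome 4, 106970462 to 106988813). Ahdc1 (chromosome 4, 133039888 to 133059960), Pmepa1 (chromosome 2, 173242817 to 173262585) and Sept9 (chromosome 11, 117306869 to 117326370) held the others, of 20.1, 19.8 and 19.5 kb. None of the 10 contained the most 5′ TSS of a protein-coding gene, but 4 of them, in Lrig1, Smad7, Ssbp3 and Sept9, contained the TSS of another annotated transcript, and at most 21.2% of any, the Notch1 domain, was exonic. Merging peaks over gaps of up to 1 kb gave 52324 domains with a median width of 641 bp, of which 885 exceeded 5 kb and 100 exceeded 10 kb. The count over 10 kb depended on the merging gap, with 0 at a gap of 0 bp and 861 at 3 kb, and it was 50 in replicate 1 alone and 110 in replicate 2 alone. The ranking depended on these too: of the 10 domains above, 2 were among the 10 widest at a gap of 0 bp, 3 at 3 kb, 5 in replicate 1 alone and 6 in replicate 2 alone.

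Regulators of the gastric mesenchyme carried more of the mark than random genes, and regulators of the gastric epithelium did not pass the test. All 22 mesenchyme regulators had a replicated peak within 25 kb of the TSS, 15 were above the upper quartile of genes, and their median was 4302 bp covered, against 908 bp for random lists matched on gene length and 1496 bp for those matched on regional GC content and gene density. Examples were Hoxa5 with 13.7 kb (11.9 ± 3.69 kb in the replicates, SD, n = 2), all of the 13.7 kb in stretches of neighbouring Hox genes, Meis2 with 8.72 kb (6.21 ± 1.65 kb, SD, n = 2), Meis1 with 7.19 kb (4.83 ± 0.153 kb, SD, n = 2) and Foxf1, a target of Hedgehog signalling in gut mesenchyme, with 6.87 kb (6.73 ± 0.957 kb, SD, n = 2). Barx1, a homeobox gene needed for stomach specification, had 3.88 kb covered (3.82 ± 1.67 kb, SD, n = 2), and its strongest peak lay 2.26 kb upstream of the TSS in intergenic sequence (chromosome 13, 48660285 to 48661199, fold 3.58). Nkx2-5 and Six2, regulators of the pyloric region, had 1.98 kb and 1.42 kb covered, and Nkx3-2 had the least of the list, 0.934 kb; in replicate 1 alone these were 925, 535 and 416 bp, and in replicate 2 alone 2615, 2075 and 1272 bp. The list ranked above 99.99% of 10000 matched random lists (permutation p = 0.0002, adjusted p = 0.00293 over 44 tests), and both replicates alone had medians above random, 3093 bp in replicate 1 and 4216 bp in replicate 2. The call was lost with a window of 5 kb (permutation test, adjusted p = 0.174, against 0.00147 to 0.0235 under the other settings).

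Components of signalling pathways that include Hedgehog, Notch, Wnt, BMP and FGF were also more heavily marked than random genes. Of 27 signalling genes, 26 had a peak, 19 were above the upper quartile, and the median was 3195 bp (2377 bp in replicate 1 and 3389 bp in replicate 2), against 997.5 bp for random lists matched on gene length and 1535 bp for those matched on GC content and gene density. Notch1, a Notch receptor, had 19.1 kb covered (15.4 ± 3.54 kb in the replicates, SD, n = 2), Ptch1, the Hedgehog receptor, 13.9 kb (11.4 ± 0.922 kb, SD, n = 2) and Sfrp1, a secreted Wnt antagonist, 12.6 kb (10.5 ± 2.11 kb, SD, n = 2). Fgf10 had no peak within 25 kb of its TSS in the replicated list or in either replicate. The list passed the test (permutation p = 0.0002, adjusted p = 0.00293).

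Among 20 epithelial regulators 17 had a peak, 2 were above the upper quartile and the median was 1126 bp (permutation p = 0.381, adjusted p = 0.917). Foxa3 had 5.07 kb covered (2792 bp in replicate 1, less than Nkx6-3, and 7338 bp in replicate 2) and Nkx6-3, a homeobox gene of the gastric antrum, 4.59 kb (4.18 ± 0.304 kb in the replicates, SD, n = 2). Sox2, which marks the foregut and stomach epithelium, had 2.57 kb (2.19 ± 0.813 kb, SD, n = 2), Gata4 2.09 kb (1.93 ± 0.208 kb, SD, n = 2), Pdx1 1.55 kb (315 bp in replicate 1 and 1252 bp in replicate 2) and Hnf4a 1.11 kb (1.06 ± 0.104 kb, SD, n = 2). Klf5, Hnf1b and Hnf4g had no replicated peak within 25 kb of the TSS. Both replicates had peaks near Klf5 (486 bp covered in replicate 1 and 973 bp in replicate 2) and Hnf1b (200 and 519 bp), and neither near Hnf4g. The median of the mesenchyme regulators exceeded that of the epithelial regulators by 3176 bp in a two-sided permutation test (p = 0.00038, adjusted p = 0.00228 over 6 pairs of lists), a comparison chosen after the list results were seen. Mature products of the gastric epithelium, such as acid-pump subunits, mucins and gastrokines, had a median of 951 bp (permutation test, adjusted p = 0.917). Random lists matched on regional GC content and gene density had a median of 2131 bp. Against these the mature products lay lower but did not pass (permutation test, adjusted p = 0.0792 for the lower tail).

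Smooth muscle genes had 15 of 16 members with a peak and a median of 2770 bp. Des had 10.6 kb covered (8.11 ± 0.530 kb in the replicates, SD, n = 2), Cald1 8.70 kb (6722 and 7981 bp in replicates 1 and 2) and Tpm1 7.10 kb (5409 and 6773 bp), and Acta2 had no replicated peak. The list ranked above 98.8% of random lists but failed the correction (permutation p = 0.0125, adjusted p = 0.138). In the same permutation test it passed in replicate 2 alone (adjusted p = 0.0143), with a 100 kb window (0.0044) and with matching on CpG class (0.0352), within a range of adjusted p from 0.0044 to 0.263 over all settings.

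Of the 22 lists, 3 were higher than random after correction and 0 were lower, against 4 and 0 at an unadjusted permutation p under 0.05, smooth muscle being the fourth. Other cell types that a stomach dissection could hold did not pass the permutation test: median covered length was 3158 bp for spleen mesenchyme genes (adjusted p = 0.520), 1528 bp for mesothelial genes (0.867), 1478 bp for endothelial genes (0.867), 998 bp for squamous epithelium genes (0.917), 913.5 bp for pancreas genes (0.917), 746.5 bp for enteric neural crest genes (0.973), 526 bp for blood cell genes (0.995), 462.5 bp for liver genes (0.995) and 451.5 bp for intestine genes (0.995). The mesothelial list held only 8 genes, and the spleen mesenchyme list only 6, all with a peak. The spleen mesenchyme median was 3.19 times that of random lists, against 3.20 times for signalling components. Random medians of 6 genes spread widely (middle 95% from 0 to 4138 bp), so failing the test does not show a lack of mark. Lists from tissues outside the dissection gave 1807 bp for forebrain genes (0.811), 1437 bp for skeletal muscle genes (0.867), 1348 bp for retina and lens genes (0.885), 1247 bp for cardiomyocyte genes (0.885) and 409 bp for germ line genes (0.995), and housekeeping genes had 2048 bp (0.520). Some medians moved between replicates 1 and 2: forebrain 1062 and 2116 bp, retina and lens 749.5 and 1335 bp, intestine 445.5 and 812.5 bp. Single members stood far above their lists: Cdx1, an intestinal homeobox gene, had 16.6 kb covered, against 3.26 kb for Cdx2 (1555 bp in replicate 1 and 2102 bp in replicate 2), and Tnnt3, Lyl1, Gnat1, Pbx1, Eng and Cpa1 had 20.9, 15.6, 13.9, 10.1, 8.96 and 8.28 kb (14710, 10207, 10931, 7442, 5055 and 6023 bp in replicate 1, the lower replicate for each). The strongest peak near Lyl1 was the one inside G430095P16Rik, and that near Gnat1 was an intronic peak of Sema3f. Windows of neighbouring genes share peaks, so none of these lengths shows that the named gene itself was marked. Which genes the peaks near Cdx1 and Tnnt3 belong to was not examined. Myod1 had 1.18 kb (214 bp in replicate 1 and 2135 bp in replicate 2), and Trp63 and Alb had no replicated peak. For 9 lists, none of which passed, the median and the mean lay on opposite sides of random: gastric epithelial regulators, mature gastric products, mesothelial, pancreas, intestine, squamous, forebrain, cardiomyocyte and posterior Hox genes. The X-linked members Gata1, Plp1, Hprt and Pgk1 had 0, 0, 0.225 and 0 kb covered, on a chromosome with few peaks.

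**Figure D1:**
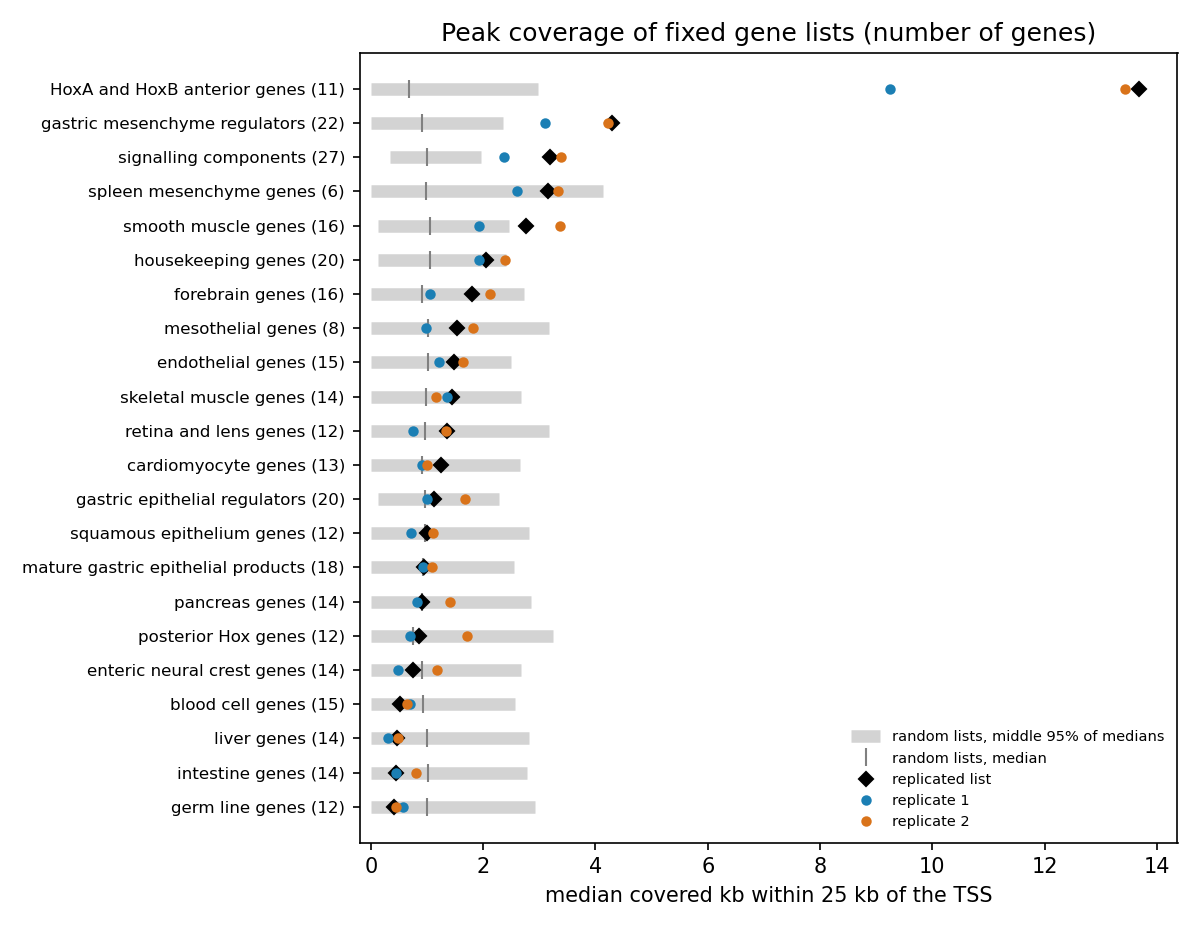
Median length covered by peaks within 25 kb of the TSS (kb) for each of the 22 gene lists, as diamonds for the replicated list and circles for each replicate, with the middle 95% and the median of matched random lists in grey. Anterior HoxA and HoxB genes (13681 bp), mesenchyme regulators (4302 bp) and signalling components (3195 bp) passed the test.

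In the Hox clusters, whose genes are ordered along the body axis, the 3′ parts of HoxA and HoxB were more heavily marked than their 5′ parts. Peaks covered 29.9% of the anterior part of HoxA and 1.70% of its posterior part, and 32.9% and 8.72% of the corresponding parts of HoxB, whose posterior part is the 3.13 kb stretch of Hoxb13 alone, with 273 bp covered (0% in replicate 1 and 10.6% in replicate 2). In HoxC the values were 9.71% and 1.0%, and in HoxD 4.68% and 7.30%. The most covered stretches in the replicated list were those of Hoxb2 (55.6%), Hoxa3 (55.5%), Hoxb3 (53.2%), Hoxa4 (39.4%) and Hoxb4 (30.5%). In the same order they had 32.8, 40.58, 33.81, 21.16 and 24.93% in replicate 1. In replicate 2 they had 41.35, 49.05, 50.95, 35.19 and 18.52%, so Hoxb2 led in neither replicate. No replicated peak lay in the stretches of the anterior genes Hoxa5, Hoxa6, Hoxd3 and Hoxd4, nor in those of Hoxa9, Hoxa10, Hoxa11, Hoxc10, Hoxc11, Hoxc12, Hoxd9 and Hoxd10. Of all these stretches, only that of Hoxd10 was uncovered in both replicates. Replicate 2 alone covered 18.1% of the Hoxa5 stretch, 6.07% of Hoxa6, 2.36% of Hoxd3 and 3.78% of Hoxd4. Of these anterior genes replicate 1 covered only Hoxa6 (2.475%). In the replicates the anterior part of HoxA was covered by 26.5 ± 6.23% and the posterior part by 2.65 ± 1.69% (SD, n = 2), and for HoxB by 24.9 ± 4.81% and 5.32 ± 7.52% (SD, n = 2). The HoxD difference, −2.62 points, was 0.802 in replicate 1 alone and −0.543 in replicate 2 alone, so its direction was not settled. The clusters lie at chromosome 6, 52155590 to 52260880 (HoxA), chromosome 11, 96194316 to 96368256 (HoxB), chromosome 15, 102921103 to 103036852 (HoxC) and chromosome 2, 74668310 to 74765142 (HoxD).

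All 11 anterior HoxA and HoxB genes were above the upper quartile of genes, with a median of 13681 bp covered against 672 bp for random lists, or 3333 bp for those matched on regional GC content and gene density. Hoxb3 had the most, 20.2 kb (15.6 ± 3.15 kb in the replicates, SD, n = 2), and Hoxa3, read at its most 5′ annotated TSS, the least, 6.17 kb (3950 bp in replicate 1 and 7965 bp in replicate 2). In replicate 2 alone Hoxb5 (6523 bp) and Hoxb6 (6723 bp) had less than Hoxa3. The list exceeded every random list (permutation p = 0.0001, the smallest they can give, adjusted p = 0.00293), but its genes lie in 2 loci with overlapping windows while random genes are scattered, which makes this p too small. Of 12 posterior Hox genes 11 had a peak, 0 were above the upper quartile, and the median was 857 bp (permutation test, adjusted p = 0.917). Their median was 691 bp in replicate 1 alone and 1716 bp in replicate 2 alone. When random lists were matched on regional GC content and gene density, the posterior list fell below random (permutation test, adjusted p = 0.0022 for the lower tail, against 0.627 to 1 under the other settings), though its 12 genes lie in 4 loci.

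**Figure D2:**
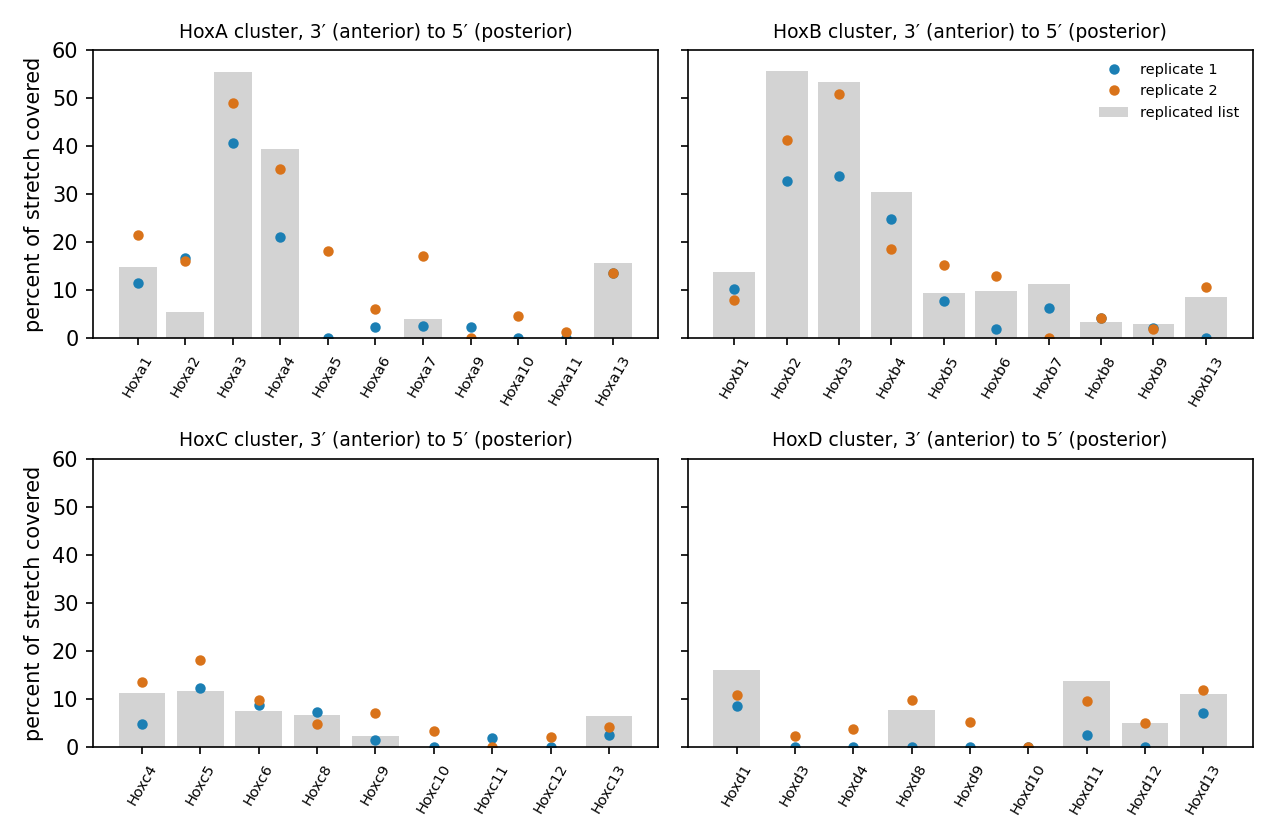
Percent of each Hox gene's stretch covered by peaks, ordered from the 3′ to the 5′ end of each cluster, as bars for the replicated list and points for each replicate. Hoxb2 (55.6%), Hoxa3 (55.5%) and Hoxb3 (53.2%) had the highest values in the replicated list.

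The mark was enriched in introns and near TSSs and depleted between genes. Introns held 43214 replicated peaks (56.8%, against 42.2% for random placements, a fold of 1.35), and 10150 peaks (13.3%) lay within 1 kb of a TSS, 3.33 times the random share. Exons beyond that distance held 5183 peaks (6.81%, fold 1.63), and intergenic sequence held 17555 peaks (23.1%, fold 0.465). The replicates gave folds over random of 2.95 ± 0.317 near TSSs, 1.36 ± 0.0157 in introns and 0.490 ± 0.0155 between genes (SD, n = 2). Against protein-coding genes only, the TSS fold was 5.69. Random placements avoided assembly gaps but not repeat-masked sequence, such as 66394619 of the 195471971 bp of chromosome 1. In the replicates, 11.5% to 12.7% of the bases of peaks, met or not met in the other replicate, were masked. The folds, and those for the replicate overlap, were not corrected for this.

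Relative to sequence 1 to 2 kb away, the mark at the TSS itself was low for CpG-rich promoters and not for CpG-poor ones. Over 9734 CpG-rich promoters, 4.04% of the centre bins and 21.6% of the flanking bins were covered, a ratio of 0.187 (0.214 ± 0.00739 in the replicates, SD, n = 2). Coverage of these promoters was highest 1150 bp downstream of the TSS, at 37.6%, and reached 18.3% upstream. Over 12021 CpG-poor promoters the ratio was 1.56 (1.60 ± 0.0166, SD, n = 2), with 7.84% at the centre and 5.04% in the flanks. Their coverage was also highest downstream, 9.71% at 850 bp from the TSS, and reached 8.14% upstream. The difference between the promoter classes was far larger than the spread between replicates. Over all annotated transcript TSSs, each given the CpG class of its gene's most 5′ TSS, the ratios were 0.331 for the CpG-rich class and 1.10 for the CpG-poor class. The upstream and downstream maxima were read at the most 5′ annotated TSS of each gene only, so how they depend on the choice of TSS was not tested.

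**Figure D3:**
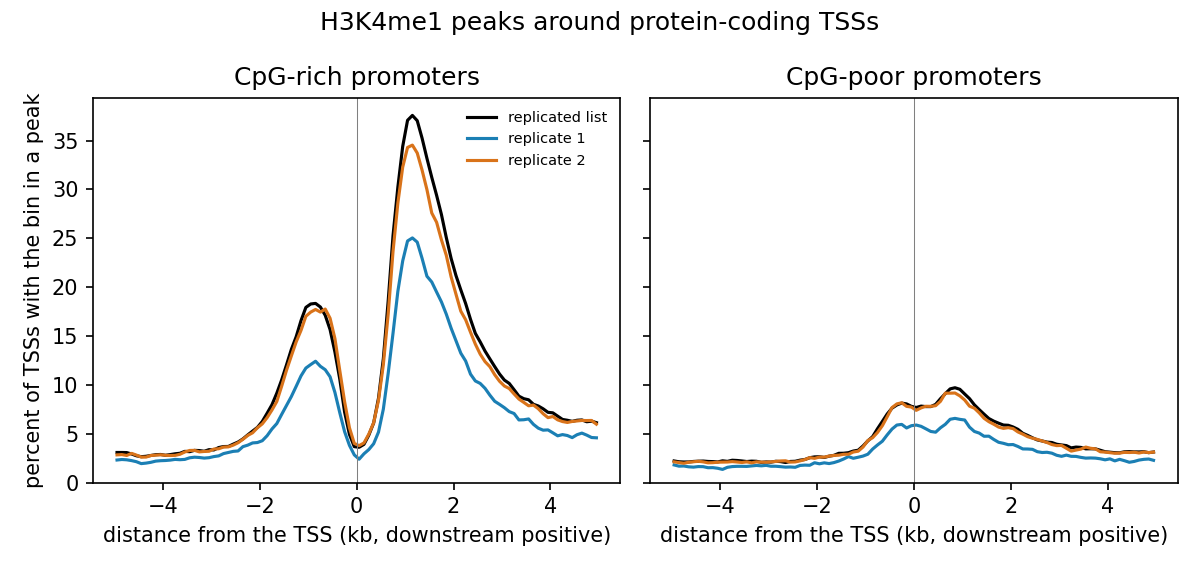
Percent of protein-coding TSSs covered by a peak, in 100 bp bins by distance from the TSS (kb), for CpG-rich and CpG-poor promoters in the replicated list and each replicate. CpG-rich promoters had their highest coverage, 37.6%, downstream of the TSS, read as the most 5′ annotated TSS of each gene.

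Peaks near and far from promoters were alike in width and strength. Median width was 495 bp within 1 kb of a TSS, 523 bp between 1 and 10 kb and 483 bp beyond 10 kb, and median folds were 3.52, 3.48 and 3.44. The ratio of the proximal to the distal median was 1.02 for width (1.07 ± 0.0223 in the replicates, SD, n = 2) and 1.02 for fold (1.03 ± 0.00301, SD, n = 2). The width ratio turned below 1 with peaks of −log10 p of at least 5 (0.978) and with peaks merged over gaps of up to 1 kb (0.997).

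The X chromosome carried few peaks. It held 229 replicated peaks, or 1.4 per Mb, against a median of 31.9 per Mb over the 19 autosomes, which ranged from 22.8 on chromosome 3 to 49.6 on chromosome 11. The autosomal median was 22.7 times the X value in the replicated list and 19.0 ± 4.01 times in the replicates (SD, n = 2). The X-linked gene with the most covered bases was Bcor, a transcriptional corepressor, with 3.96 kb (1.97 kb in replicate 1), followed by Tmem164, Atp7a, Fgd1 and Lage3, though in replicate 2 alone Tmem164 had more than Bcor, 3.24 against 3.05 kb. These X-linked genes were picked after their values were seen.

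**Figure D4:**
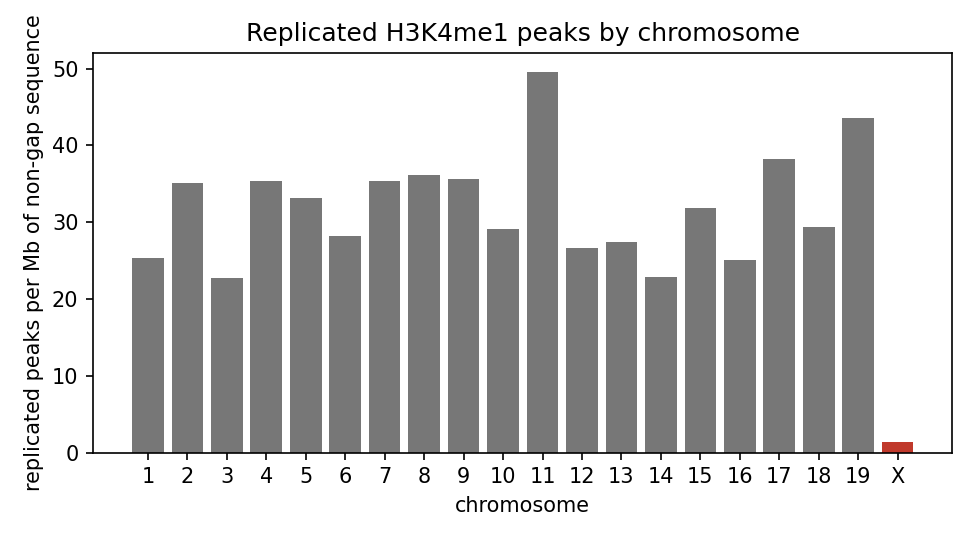
Replicated peaks per Mb of sequence outside assembly gaps on each chromosome, as bars. The X had 1.4 replicated peaks per Mb, below every autosome.

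The strongest peaks of each replicate were met in the full list of the other more often than its weakest. Of replicate 1 peaks 46.3% were met in replicate 2 (Wilson 95% interval 46.0 to 46.5%), and of replicate 2 peaks 41.6% were met in replicate 1 (41.3 to 41.9%), 19.2 and 17.7 times the shares after random placement, 2.41 ± 0.0497% and 2.35 ± 0.0410% (SD, n = 20 placements). In the decile of peaks with the highest −log10 p, 83.1% of replicate 1 and 84.2% of replicate 2 were met, against 31.4% and 21.1% in the lowest decile. Median width was 511 and 715 bp in the highest decile, against 228 and 226 bp in the lowest. Random placement was not split by decile, so strength and width were not told apart. With both lists cut at a −log10 p of at least 5 the shares met were not higher than in the full lists, 45.2% for replicate 1 and 37.7% for replicate 2. Shared sequence amounted to 18.8 Mb, 48.6% of the bases covered in replicate 1 and 39.9% of those in replicate 2. Across 51735 pairs of shared peaks, Spearman's rho was 0.215 for fold, a correlation across peaks, which are not independent replicates.

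**Figure D5:**
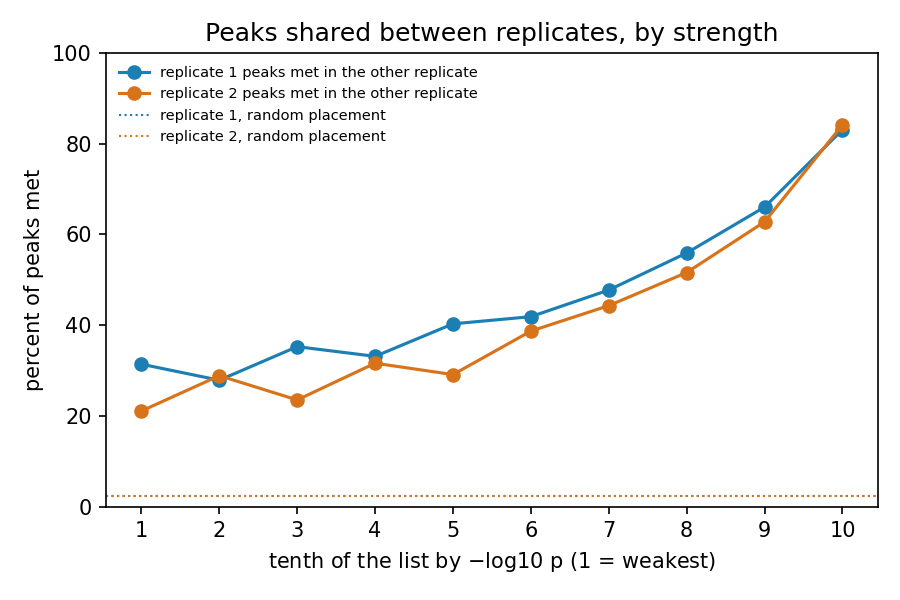
Percent of each replicate's peaks met in the other replicate, by decile of −log10 p from weakest to strongest, with dotted lines for random placement. The share was 31.4% in the weakest and 83.1% in the strongest decile of replicate 1, and 21.1% and 84.2% in those of replicate 2.

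The replicated list kept 55.3% of the pooled peaks and dropped 61448. Kept peaks had a median width of 499 bp and a median fold of 3.44, against 249 bp and 2.70 for dropped peaks. All 49922 pooled peaks that met both replicates were kept, and they made up 65.6% of the list. Of pooled peaks that met 1 replicate, 9359 of 27211 for replicate 1 and 14351 of 36941 for replicate 2 were kept, as were 2470 of 23476 that met neither at 50% of either peak.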

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

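The alternatives matched on regional GC content and gene density, without X-linked genes, with annotated Hox gene bodies and with the pooled list for chromosomes were chosen after seeing the data. Of 107 recomputed values of the main results, 46 stayed within a set margin or on the same side of the threshold, 58 moved by more and 3 changed direction, and the cause was not tested. The margin was the spread of the replicates, except for shares of peaks met or kept, Spearman's rho and counts. For these it was the reach of the Wilson interval, an interval from the number of pairs and a fixed factor, so many moves were small. Of 328 further values, 279 were the same, 1 fell short of the threshold, 4 passed it and 44 moved, the last all for named genes (96 values, of which 52 stayed within the spread). The width ratio of proximal to distal peaks changed direction with peaks of −log10 p of at least 5 (0.978) and with merged peaks (0.997), and its values without a replicate ran from 1.06 to 1.09. The ratio of folds ran from 1.029 to 1.033 without a replicate. In HoxD the anterior minus posterior difference was −0.237 with the stricter peaks, −8.85 over gene bodies, and ran from −0.543 to 0.802 without a replicate. For HoxA it ran from 20.7 to 27.1 and for HoxB from 17.7 to 21.5 without a replicate, and for HoxB it was 20.7 with the stricter peaks and 27.6 over gene bodies. For HoxC it was 4.64 over gene bodies.

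Overlap rules moved the share of replicate 1 peaks met from 46.3% to 55.0% (1 bp) and 25.2% (50% of both peaks), and that of replicate 2 from 41.6% to 50.3% and 24.5%. With stricter peaks these were 45.2% and 37.7%, with the top 50% of the shorter list 43.9% and 40.6%, and rho was 0.249 for −log10 p. The replicated list kept 84.3% of pooled peaks with a −log10 p of at least 5, and 75.8% of those kept met both replicates. With overlaps of 1 bp, 66.7% of all kept peaks met both. Folds over random for TSS-proximal, exonic, intronic and intergenic peaks were 2.86, 1.2, 1.2 and 0.443 with promoters of 2500 bp, and 5.69, 1.73, 1.46 and 0.515 with protein-coding genes only. By covered bases the intronic and intergenic folds were 1.4 and 0.430, and with stricter peaks the intergenic fold was 0.442. Without a replicate they ran from 2.73 to 3.18, 1.55 to 1.63, 1.35 to 1.37 and 0.479 to 0.501. Centre to flank ratios for all, CpG-rich and CpG-poor promoters were 0.446, 0.164 and 1.47 with stricter peaks and 0.547, 0.331 and 1.10 over all transcript TSSs, and ran from 0.535 to 0.540, 0.209 to 0.220 and 1.59 to 1.62 without a replicate. Transcript TSSs took the CpG class of their gene's most 5′ TSS. Domains over 10 kb numbered 0 at a gap of 0 bp and 861 at 3 kb, and 50 to 110 without a replicate. The X ratio was 31.5 with stricter peaks and 18.5 in the pooled list, and ran from 16.1 to 21.8 without a replicate. Matching on GC content and gene density left 3 lists higher and made 1 lower, the posterior Hox genes. Read depth was not given, so which weak peaks it left uncalled was not tested.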

Other observations

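The tests on symbol families, on pairs of gene lists and on explanations were chosen only after the result was seen, except the test on repeat-masked sequence, whose outcome was unknown when it was chosen. The motif comparison was planned.

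Outside the fixed lists, 122 families of genes with a common symbol root and at least 15 loci were compared with matched random lists as an exploratory step. After correction 12 families were higher than random (Bcl, Tmem, Tspan, Map, Cdc, Wnt, Rps, Arhgap, Rpl, Sema, Arhgef and Ppp), and 4 of them, Bcl, Tspan, Map and Cdc, were also higher when random lists were matched on regional GC content and gene density. Bcl9l, a Wnt pathway coactivator, had 17.4 kb covered within 25 kb of its TSS, Map3k1, a stress-kinase activator, 14.3 kb, Cdc42ep1 13.6 kb and Tspan14 12.0 kb. The olfactory receptors (Olfr), vomeronasal receptors (Vmn), cytochromes P450 (Cyp) and zinc finger proteins (Zfp) were lower than random, but 0 of these passed with GC content and gene density matched, where Krt and Ccl, which had not passed before, were lower (permutation test, adjusted p = 0.0390 each).

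Of the 6 pairs of gene lists compared, smooth muscle genes exceeded mature gastric products by 1818 bp (permutation p = 0.0112, adjusted p = 0.0168) but did not pass against skeletal muscle genes (permutation p = 0.127, adjusted p = 0.127). The pairs were not matched on regional GC content and gene density. Random lists matched on these had medians of 1647 bp for smooth muscle genes and 2131 bp for mature gastric products.

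Sequence in distal peaks was compared with windows 5 kb to one side, in 35004 pairs of 400 bp. The FOX consensus TGTTTAC was found in 8.22% of peaks and 5.21% of side windows, the TEAD consensuses in 24.9% and 20.0%, the E-box CAGCTG in 30.6% and 17.3%, and the palindromic NFI site in 60 peaks and 7 side windows. The TEAD shares are those of GGAATG alone, since every match to the other TEAD consensus, ACATTCC, contains it on the opposite strand. The FOX, TEAD, E-box and NFI ratios, 1.58, 1.24, 1.77 and 8.57, exceeded those of all 100 shuffles drawn for each family. The p of these 4 families, 0.0099, is the smallest that 100 shuffles can give. After correction over 24 tests it became 0.0594, so 0 families passed, against 5 higher and 0 lower at an unadjusted p under 0.05. Shuffles were drawn with repeats, and CAGCTG has fewer than 100 distinct ones, so the p of the E-box is too small. The 2 TEAD consensuses were shuffled separately, so their shuffles lack the overlap of the consensuses. The 8 families besides FOX, TEAD, E-box and NFI (GATA, SOX, AP-1, HNF4, CTCF, SRF, NKX and HOX/MEIS) had ratios from 0.867 to 1.2. Peaks had a GC content of 49.0% and side windows 44.7%.

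Few peaks lay on the X chromosome, where autosomes had 22.7 times as many per Mb. The intervals given below for observed ratios cover the counting error of the X peaks only, not the spread between replicates. A lower copy number of X DNA in a pool of equal numbers of male and female embryos was argued against as the whole cause: scaling the folds of autosomal peaks of the pooled list by 0.75 gave an expected ratio of 4.10, against 19.5 observed above the median fold (interval 17.1 to 22.8; with peaks on the even steps of fold only, 4.63 against 10.1), and thinning their summits to 0.75, with each step of fold read as 1 fragment although 42.1% of autosomal and 86.5% of X peaks lay on the steps, gave 3.04, against 16.8 observed above 19 fragments, the median of all autosomal peaks (interval 14.9 to 19.1). A lack of CpG-rich promoters was also argued against as the whole cause, since 25.6% of X genes with a CpG-rich promoter had a peak within 25 kb, against 91.7% on autosomes, and so were repeats, since the 16.8 was counted per Mb outside repeats and gaps. Sites on the X at 0.5 of the autosomal height were left open: thinning to 0.5 gave a ratio of 25.7, above the 16.8 observed, and scaling folds by 0.5 gave 92.6, above the 19.5. Above the lower quartile of height, thinning lay within the observed interval in the pooled list (15.7, interval 13.2 to 16.1). It did so too in replicate 1 (19.7, interval 15.7 to 20.1), but fell short in replicate 2 (10.6 against 13.4). Above the median height, thinning to 0.5 exceeded the interval in both replicates (30.87, interval 18.61 to 25.93, in replicate 1). Above the upper quartile it did so in every list, with 61.95 in the pooled list (interval 22.76 to 36.79). There replicate 1 gave 47.71 (23.42 to 37.48) and replicate 2 gave 37.46 (22.44 to 36.81). The criterion of lying within the interval was set after the values were seen. No single height was fitted, and what would lower it (sex composition of the pool, X inactivation, or how the control was scaled, on which the unequal shares on the steps may bear) was not tested and stays open.

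Mesenchyme regulators and signalling components stood above random lists. Their regional GC content and gene density were argued against as the whole cause but may account for part, because both lists passed with random lists matched on these, whose medians rose from 908 to 1496 bp and from 997.5 to 1535 bp (permutation test, larger adjusted p = 0.022, that of the signalling components, which ranged from 0.00147 to 0.022 over their alternatives). An equal mark at forebrain genes was argued against for the mesenchyme regulators, within 25 kb only. Their median exceeded that of forebrain genes by 2495 bp (two-sided permutation p = 0.00562, adjusted p = 0.0112 over 6 pairs). Signalling components exceeded forebrain genes by 1388 bp (permutation p = 0.0316, adjusted p = 0.0379). Forebrain genes were the only such comparison, so a mark shared by developmental regulators of other organs stays open. The 6 spleen mesenchyme genes, which were not compared, had a median of 3158 bp, 3.19 times that of random lists. In replicates 1 and 2 alone the forebrain median was 1062 and 2116 bp, and that of the mesenchyme regulators 3093 and 4216 bp. Within 5 kb the medians lay close together, 937.5 bp for mesenchyme regulators and 887.5 bp for forebrain genes. Their difference was not tested, so an equal mark at forebrain genes stays open there. A larger share of mesenchymal than epithelial cells in the dissected stomach is a candidate explanation that these lists alone leave untested.

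Many peaks of 1 replicate were not met in the other. Peaks in repeat-masked sequence were argued against, since the masked share of peaks not met was at most 1.10 times that of peaks met (12.7% and 11.5% in replicate 1). Calls near the threshold at low depth may account for many of them, since at least 83.1% of the decile of peaks with the highest −log10 p was met in the full list of the other replicate. However, that decile also had the largest median width, and with both lists cut at a −log10 p of at least 5 the shares met were 45.2% and 37.7%, so how many stays open. No biological explanation was tested, as the design has 1 group. The different number of control alignments, 2 for replicate 1 and 1 for replicate 2, stays open.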
